A study of Homo sapiens with 14 samples.

How the data were processed

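RNA of LY2 breast cancer cells was measured on 14 Affymetrix HG-U133 Plus 2.0 arrays. Per the labels' protocols, cells were kept in medium with 10 nM 4-hydroxytamoxifen, grown without it for 72 hours, and transfected with 40 nM siRNA against SRC-1 or a scrambled siRNA. After 24 hours they received 100 nM 4-hydroxytamoxifen or ethanol for 2 hours. RNA was extracted, treated with DNase, amplified with a NuGEN Ovation kit and labelled with biotin. Labels call the replicates biological, and nothing further is said about separate cultures. P-values therefore measure the spread between these arrays.

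The deposited values are on a log2 scale, with 1 value per probe set and array, made by the authors. The base was inferred from the range of the values, which fits that of a scanner. Background correction, normalization and summary method are not given in the sources used here, and the submitters' processing notes name only R 2.9.2. Quartiles were nearly equal across arrays, and low signals formed a dense floor near 2, where differences are compressed. Values were used as deposited. The whole table was analysed except 62 array control probe sets, leaving 54613 of 54675. Of these, 41091 carried 1 gene symbol, 1801 several and 11721 none in the annotation used here.

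Samples were grouped by siRNA and treatment from the labels. A linear model with 4 group means over all 14 arrays was fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3) using lmFit and eBayes. Adjusted p is by Benjamini-Hochberg over the 54613 probe sets, two-sided, with a threshold of 0.05. Contrasts were the knockdown in untreated and in tamoxifen-treated cells, tamoxifen in control-siRNA and in SRC1-siRNA cells, and their interaction, and an additive model gave the knockdown over both treatments. The level of NCOA1 was also compared by an exact two-sided permutation test of its mean over probe sets. Where a group of 2 arrays was reduced to 1 by leaving out an array, the lone array was assumed to vary like the other groups.

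The gene lists, the tests of the comparisons, lists and NCOA1, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are the 10 higher and 10 lower genes with the largest change in each comparison, among passing probe sets with 1 symbol and a mean above the median of all probe sets (3.47), along with NCOA1, list members that passed, and up to 4 members of each list with the smallest p. The 26 lists held 521 genes, of which 468 were measured and 53 were not analysed here. Each gene was represented by its brightest probe set. Lists were tested with camera at a preset correlation of 0.01, adjusted over 26 lists and 4 comparisons, 104 tests. At that setting 15 tests passed, and with an estimated correlation 0 did. Members were counted over all probe sets and adjusted over the list alone. Markers of fibroblasts, immune cells and endothelium stood for other cell types.

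The alternatives were leaving out dim probe sets, quantile normalization, median centring, the replicate number as a term, a fit of only the arrays compared, eBayes with trend and robust, array weights, the mean of a gene's probe sets, fry in place of camera, and leaving out each array. Chosen after seeing the data were leaving out all arrays of each replicate number, 5 further gene lists, and the simulation and F statistic of the replicate number. So were those tests of explanations that are named as such below. Tests of those 5 lists were adjusted among themselves, apart from the tests of the fixed lists. The replicate numbers were found to differ less than independent arrays would, as after differences between them had been removed from the values. No such step is stated in the sources used here. If it was done, the fit without the number as a term counts too many residual degrees of freedom and its p-values are too small. The fit with the term is then the stricter and better calibrated of both. Changes in comparisons with the SRC1-siRNA tamoxifen group, which lacked some replicate numbers, may then be shifted too. They are quoted below from the fit without the term. For the knockdown in tamoxifen-treated cells, the median of interferon response genes was 0.85 without the term and 0.79 with it. In untreated cells it was 1.31 in both fits.

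The code was tested on simulated data of the same design, with 200 changed probe sets of 54613. For the knockdown in untreated cells it recovered 66% of changes of 0.5 and 100% of changes of 1, 2 and 4 on the log2 scale, with 8 false calls among 191. For tamoxifen in control-siRNA cells it recovered 62%, 98%, 100% and 100%, with 7 false calls among 187. For tamoxifen in SRC1-siRNA cells it recovered 50%, 94%, 98% and 100%, with 8 false calls among 179. These simulated arrays held independent noise, without the structure of the replicate numbers.

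Other splits of the arrays were counted exhaustively where there were 35, and 100 were drawn for the additive fit. The highest count among the other splits of that fit depended on the draw. In 4 draws and 1 run over every split made while the work was done, it lay between 1 probe set and over 60% of the real count, and the real split was highest each time.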

Results

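Gene expression was measured in LY2 cells, a breast cancer line derived from the estrogen-dependent MCF-7 line that keeps growing in the presence of anti-estrogens. The study asked which genes depend on the nuclear receptor coactivator SRC-1 (gene NCOA1) in such endocrine-resistant cells. Cells received an siRNA against SRC-1 or a scrambled control siRNA, and were then given 4-hydroxytamoxifen, the active metabolite of the anti-estrogen tamoxifen, or its vehicle for 2 hours. The 14 arrays formed 4 groups: 4 arrays of control siRNA untreated, 4 of control siRNA with tamoxifen, 4 of SRC1 siRNA untreated and 2 of SRC1 siRNA with tamoxifen. Values are the deposited log2 signals of 54613 probe sets, and every change below is a difference of log2 group means with its standard error. The median signal of an array lay between 3.44 and 3.51. Arrays have no read depth, so their number limits the precision.

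Arrays that carried the same replicate number did not resemble each other once the group means were taken out: 18 pairwise correlations ran from -0.633 to 0.0445, with a median of -0.353. The F statistic of the replicate number lay in the lowest 5% of its null distribution for 77.8% of the probe sets, and for 5.13% in simulated arrays with no number effect. Its median was 0.0428, where 0.871 is the null value. Replicate numbers therefore differed less than independent arrays would, and the count of probe sets in each comparison is followed by the count from a fit with the replicate number as a term. Counts of list members come from the fit without that term unless stated.

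The siRNA lowered its target. NCOA1, averaged over its 4 probe sets, was at 7.70 ± 0.36 (SD, n = 4) in untreated SRC1-siRNA cells and at 9.00 ± 0.25 (SD, n = 4) in untreated control-siRNA cells, a level 59.4% lower (exact two-sided permutation p = 0.0286, the smallest that 70 regroupings allow). With tamoxifen it was at 7.74 ± 0.25 (SD, n = 2) against 9.06 ± 0.18 (SD, n = 4), a level 60.0% lower (exact two-sided permutation p = 0.133, the smallest that 15 regroupings allow). All 4 probe sets passed the limma test in both comparisons, with and without the replicate number as a term, but without SRC1 siRNA tamoxifen replicate 3 not all 4 passed in treated cells (mean change -1.15, highest limma adjusted p = 0.0555). Between untreated arrays of the same number the differences were -0.80, -1.60, -2.00 and -0.79 for replicates 1 to 4. The permutation tests regrouped arrays freely over the replicate numbers, so their p-values may be too small if differences between numbers had been removed. None of the 4 probe sets passed for tamoxifen, in control-siRNA or in SRC1-siRNA cells.

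**Figure D1:**
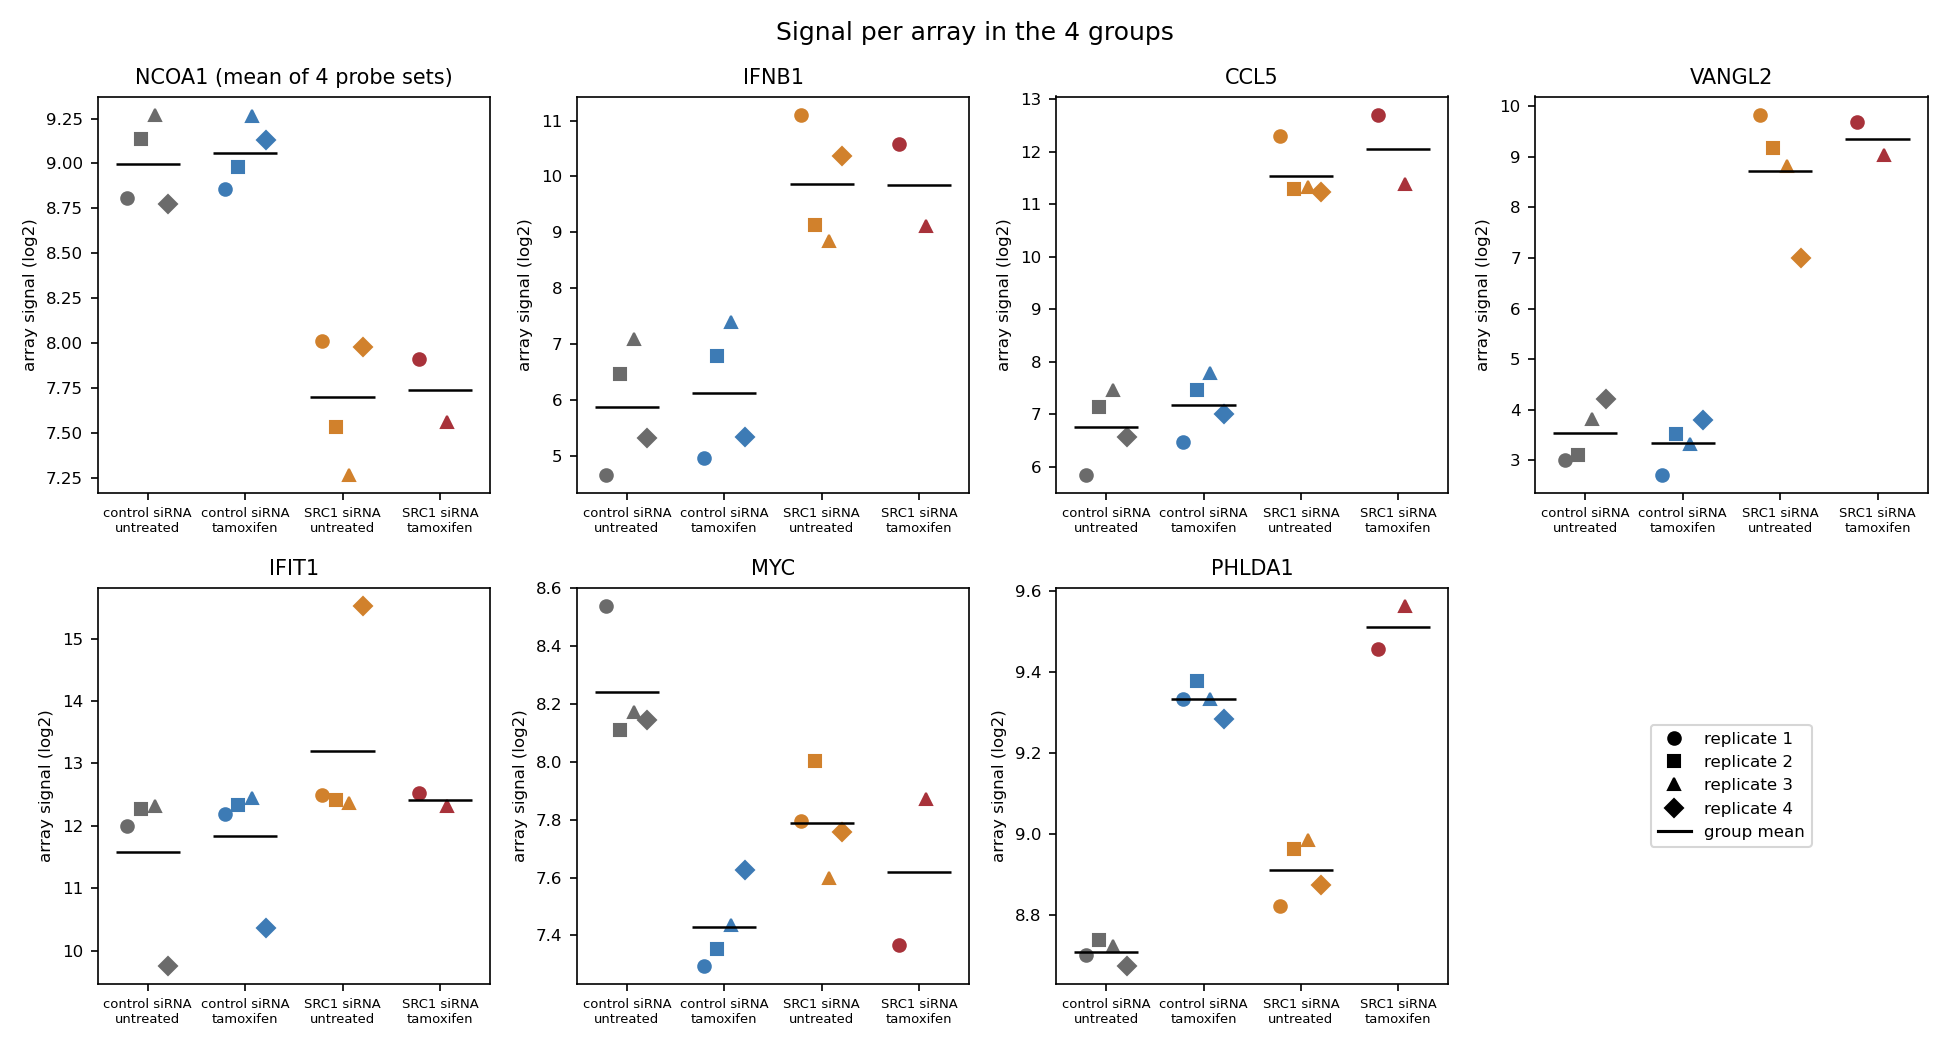
Array signal (log2, vertical axis) of NCOA1, IFNB1, CCL5, VANGL2, IFIT1, MYC and PHLDA1 in the 4 groups, with 1 symbol per array, shaped by replicate number, and a line at the group mean. NCOA1 is the mean of 4 probe sets and was below 8.01 in every SRC1-siRNA array and above 8.77 in every control-siRNA array.

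The comparison of SRC1 siRNA with control siRNA in untreated cells asked what loss of SRC-1 changed without tamoxifen. The largest rises were in VANGL2, a planar cell polarity protein (5.17 ± 0.48, adjusted p = 2.22e-04), the chemokine CCL5 (4.87 ± 0.50, adjusted p = 3.58e-04) and the sodium channel subunit SCN3A (4.81 ± 0.59, adjusted p = 6.02e-04). Next came the chemokine CXCL11 (4.64), the MHC class II genes HLA-DRA (4.41) and HLA-DPA1 (4.03), their invariant chain CD74 (4.33), interferon beta itself, IFNB1 (3.98), the acyltransferase PLAAT4 (3.93) and the adhesion molecule CEACAM1 (3.80). Falls were smaller. They were led by ACO1, cytosolic aconitase and iron regulatory protein (-1.71 ± 0.19, adjusted p = 3.74e-04), the transcription factor NFIA (-1.52 ± 0.18, adjusted p = 5.61e-04) and the actin regulator RFLNB (-1.46). NCOA1 followed, with the non-coding RNA LINC01963 (-1.40), the hydrolase NUDT16 (-1.39), REEP1, which shapes the endoplasmic reticulum (-1.36), the mitochondrial phosphate carrier SLC25A3 (-1.34), SSR1 of the translocon-associated complex (-1.26) and the GDNF co-receptor GFRA1 (-1.26). All of these 20 genes also passed with the replicate number as a term. The size of some rises varied between replicate numbers. Between untreated arrays of the same number, VANGL2 differed by 6.83, 6.06, 5.01 and 2.79 for replicates 1 to 4. SCN3A differed by 6.68, 5.66, 5.03 and 1.87 and CD74 by 6.28, 5.07, 3.98 and 1.97, each lowest in replicate 4. The differences of CXCL11, PLAAT4 and IFNB1 were lowest in other replicates. SCN3A was at the array floor in control cells (1.96), where differences are compressed, so its change is a lower bound and its rank is uncertain. The rank of ACO1, which fell to 3.11, below the median signal, is uncertain too. The NFIA value is that of its most changed probe set. Its brightest probe set differed less, by -0.70, -0.66, -0.52 and -0.37 for untreated replicates 1 to 4.

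In all, 5653 probe sets passed, 2724 higher and 2929 lower, for 1770 and 1886 genes (727 and 730 with the replicate number as a term). Of these, 389 were at least 2-fold higher and 51 at least 2-fold lower, and 42 were at least 8-fold higher and 0 at least 8-fold lower. With the replicate number as a term 2154 passed, of which 2148 were among the 5653. The count was 3626 without SRC1 siRNA untreated replicate 1 and 3649 without SRC1 siRNA untreated replicate 2.

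Interferon response genes rose as a list: of 28 measured members 14 were higher and 0 lower, or 26 and 0 adjusted over the list alone, with a median of 1.31 (camera adjusted p = 6.82e-12; adjusted p = 0.710 with an estimated correlation). With fry in place of camera the adjusted p was 0.0514, so that the call ended there as well as with the estimated correlation. Examples were the antiviral GTPases MX1 (1.36) and MX2 (2.80), the exonuclease ISG20 (2.70), the ISG15 ligase HERC5 (3.20), the oligoadenylate synthetase-like OASL (2.80) and the chemokine CXCL10 (3.13). In the fit with the replicate number as a term 6 members were higher, MX1, MX2, ISG20, HERC5, OASL and IFI35, and CXCL10 did not pass. The arrays of replicate 4 stood apart for this list. Between untreated arrays of the same number, the list mean differed by 1.55, 0.61, 0.43 and 3.64 for replicates 1 to 4, and IFIT1, an RNA-binding antiviral protein, by 0.50, 0.13, 0.04 and 5.77. Without the 3 arrays of replicate 4 the median was 0.54, and 7 members were higher and 0 lower (camera adjusted p = 3.50e-11; adjusted p = 0.804 with an estimated correlation). IFNB1 differed by 6.45, 2.67, 1.76 and 5.04 and the brightest CCL5 probe set by 6.45, 4.15, 3.86 and 4.66, so that both were higher in SRC1-siRNA cells at every number.

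**Figure D2:**
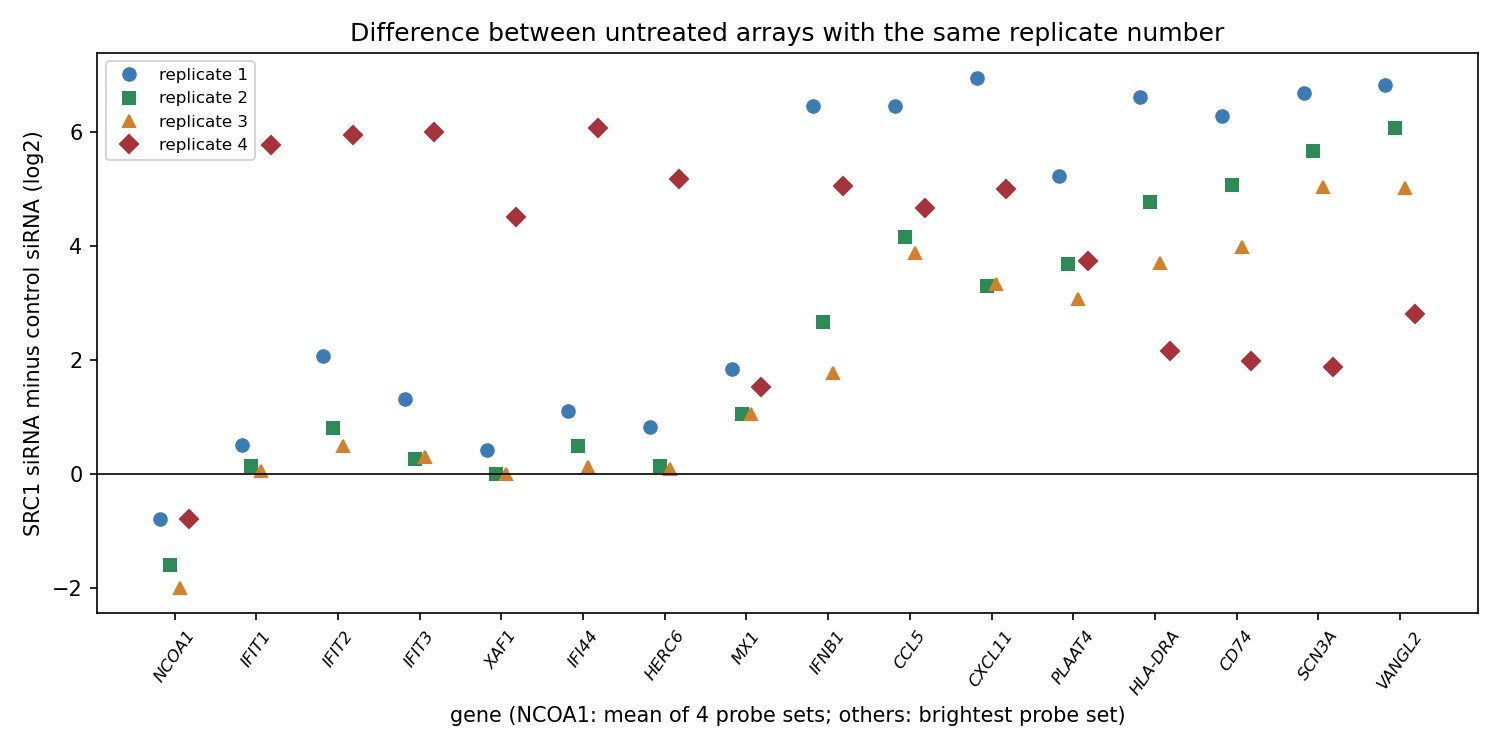
Difference in array signal between SRC1 siRNA and control siRNA (log2, vertical axis) for untreated arrays that carry the same replicate number, with 1 symbol per number for each gene on the horizontal axis. IFIT1 differed by 5.77 in replicate 4 and by 0.50 or less in the others, whereas CCL5 differed by 3.86 or more in all 4.

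Genes of the immediate early response, which growth factors and stress switch on within minutes, had 6 of 22 members higher and 0 lower, also adjusted over the list alone (median 0.32, camera adjusted p = 4.20e-04; adjusted p = 0.710 with an estimated correlation, and 0.0989 with fry). Among them were the transcription factors ATF3 (1.55), EGR3 (1.51) and KLF4 (1.05), which with MCL1 were the 4 to pass with the replicate number as a term. Of 20 genes of the unfolded protein and amino acid response, 7 were higher and 1 lower, or 10 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 1.97e-04; adjusted p = 0.127 with an estimated correlation). The lipoprotein receptor VLDLR (0.81) and PPP1R15A (0.99), which reverses translational arrest, rose and the mannosidase-like EDEM1 (-0.22) fell; with the term 3 passed, VLDLR, PPP1R15A and CEBPB, and EDEM1 did not. Histone genes had 4 of 10 members higher and 0 lower, or 6 and 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.00206; adjusted p = 0.273 with an estimated correlation), among them H2BC5 (0.45) and the dim H3C2 (0.42, below the median signal in all groups), the 2 that passed with the term. NRF2 targets, which protect against oxidants, had 3 of 16 members higher and 0 lower, also adjusted over the list alone (median 0.12, camera adjusted p = 0.0296; adjusted p = 0.710 with an estimated correlation), namely HMOX1 (0.92), AKR1B10 (0.99, from a dim 3.27) and SLC7A11 (0.67), of which SLC7A11 did not pass with the term. That call ended without control siRNA untreated replicate 1 (adjusted p = 0.134) and without SRC1 siRNA untreated replicate 1 (adjusted p = 0.0762), with fry (adjusted p = 0.0660) and without the arrays of replicate 4 (adjusted p = 0.0596), within a range of 0.00771 to 0.710 over all fits. Targets of the aryl hydrocarbon receptor had 1 of 10 members higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.0316; adjusted p = 0.273 with an estimated correlation). The member that passed over all probe sets was the oxygenase CYP1A1 (0.72), which did not pass with the term, and without the arrays of replicate 4 the list had a median of 0.16 and an adjusted p of 0.0504. Mitosis genes had 3 of 22 members lower and 0 higher, also adjusted over the list alone (median -0.14, camera adjusted p = 0.00126; adjusted p = 0.710 with an estimated correlation, and 0.0760 with fry): the checkpoint kinase BUB1B (-0.35), AURKA (-0.21) and BIRC5 (-0.16), none of which passed in limma with the term (5 of 22 had an unadjusted p under 0.05). The control siRNA untreated replicate 4 array had the lowest mean of this list in its group, 10.1 where the nearest other array was at 10.4. Without the arrays of replicate 4 the median was -0.23, with 6 members lower and 0 higher (camera adjusted p = 5.52e-06; adjusted p = 0.804 with an estimated correlation).

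The remaining lists did not pass in untreated cells, with adjusted p between 0.710 and 0.996 with an estimated correlation. Genes reported as SRC-1 dependent, a list that may include genes chosen on these samples and so is not independent evidence of a direction, had 3 of 16 members higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.870). The neurotrophin receptor NTRK2 (-0.83), the transcription factor POU3F2 (-0.66), MYC (-0.45) and ADAM22 (-0.41) fell, and the cytokine CSF1 (0.76), the integrin ITGA5 (0.64) and ERRFI1 (0.31) rose. NTRK2 and CSF1 had a group below the median signal, and MYC and ITGA5 did not pass with the replicate number as a term. Of 22 neuronal differentiation genes 1 was higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.197), with MAP2 higher (0.54) and the adhesion molecule NCAM1 (-0.75) and the neurofilament NEFH (-0.56) lower. Of 28 estrogen-induced genes 3 were higher and 2 lower, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.870). Of 17 nuclear receptor coregulators NCOA7 (0.93) was higher and TRIM24 (-0.68) lower (camera adjusted p = 0.884). Of 21 growth factor receptor signalling genes 4 were higher and 3 lower, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.664), with the feedback inhibitor SPRY2 higher (0.87) and the receptors FGFR1 (-0.65), INSR (-0.46) and ERBB4 (-0.44) lower. Of 26 ADAM and matrix metalloprotease genes 1 was higher and 2 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.884), with the sheddase ADAM17 higher (0.34) and the inhibitor TIMP3 lower (-0.56). Of 17 p53 targets 5 were higher and 2 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.205), led by the BH3-only protein PMAIP1 (1.11). Members that passed with the term were 1 higher and 5 lower for neuronal differentiation, 2 and 1 for estrogen-induced genes, 1 and 1 for coregulators, 3 and 3 for growth factor receptor signalling, 1 and 2 for ADAM and matrix metalloprotease genes and 2 and 0 for p53 targets, including all named here.

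Of 20 luminal epithelial markers 2 were higher and 2 lower (camera adjusted p = 0.988), and of 18 basal and mesenchymal markers 3 were higher and 0 lower (camera adjusted p = 0.197), namely CAV1 (1.26), FN1 (0.92) and CAV2 (0.51). DNA replication genes had 0 of 22 members higher and 3 lower, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.319), and cholesterol synthesis genes 1 of 16 higher and 1 lower (camera adjusted p = 0.870). Hypoxia and glycolysis genes had 2 of 21 higher and 4 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.870). Heat shock genes had 2 of 16 members higher and 0 lower (camera adjusted p = 0.870), and small RNA pathway genes, through which siRNAs act, 0 of 12 higher and 3 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.261), with AGO1 at -0.25. No ribosomal protein gene of 19 passed the limma test, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.889). Mitochondrial respiratory chain genes had 0 of 24 members higher and 2 lower (camera adjusted p = 0.249). For markers of other cell types, 0 of 15 fibroblast markers passed the limma test, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.610). Of 14 immune cell markers 1, CD74, was higher (camera adjusted p = 0.148), and of 11 endothelial markers 1, PECAM1 (0.73, from a dim 2.89), was higher (camera adjusted p = 0.870). Of the members counted in this paragraph, those that passed with the replicate number as a term were OVOL2, FN1, CAV2, KDM3A, ANKRD37, ALDOC, EGLN3, DNAJB4 and CD74.

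**Figure D3:**
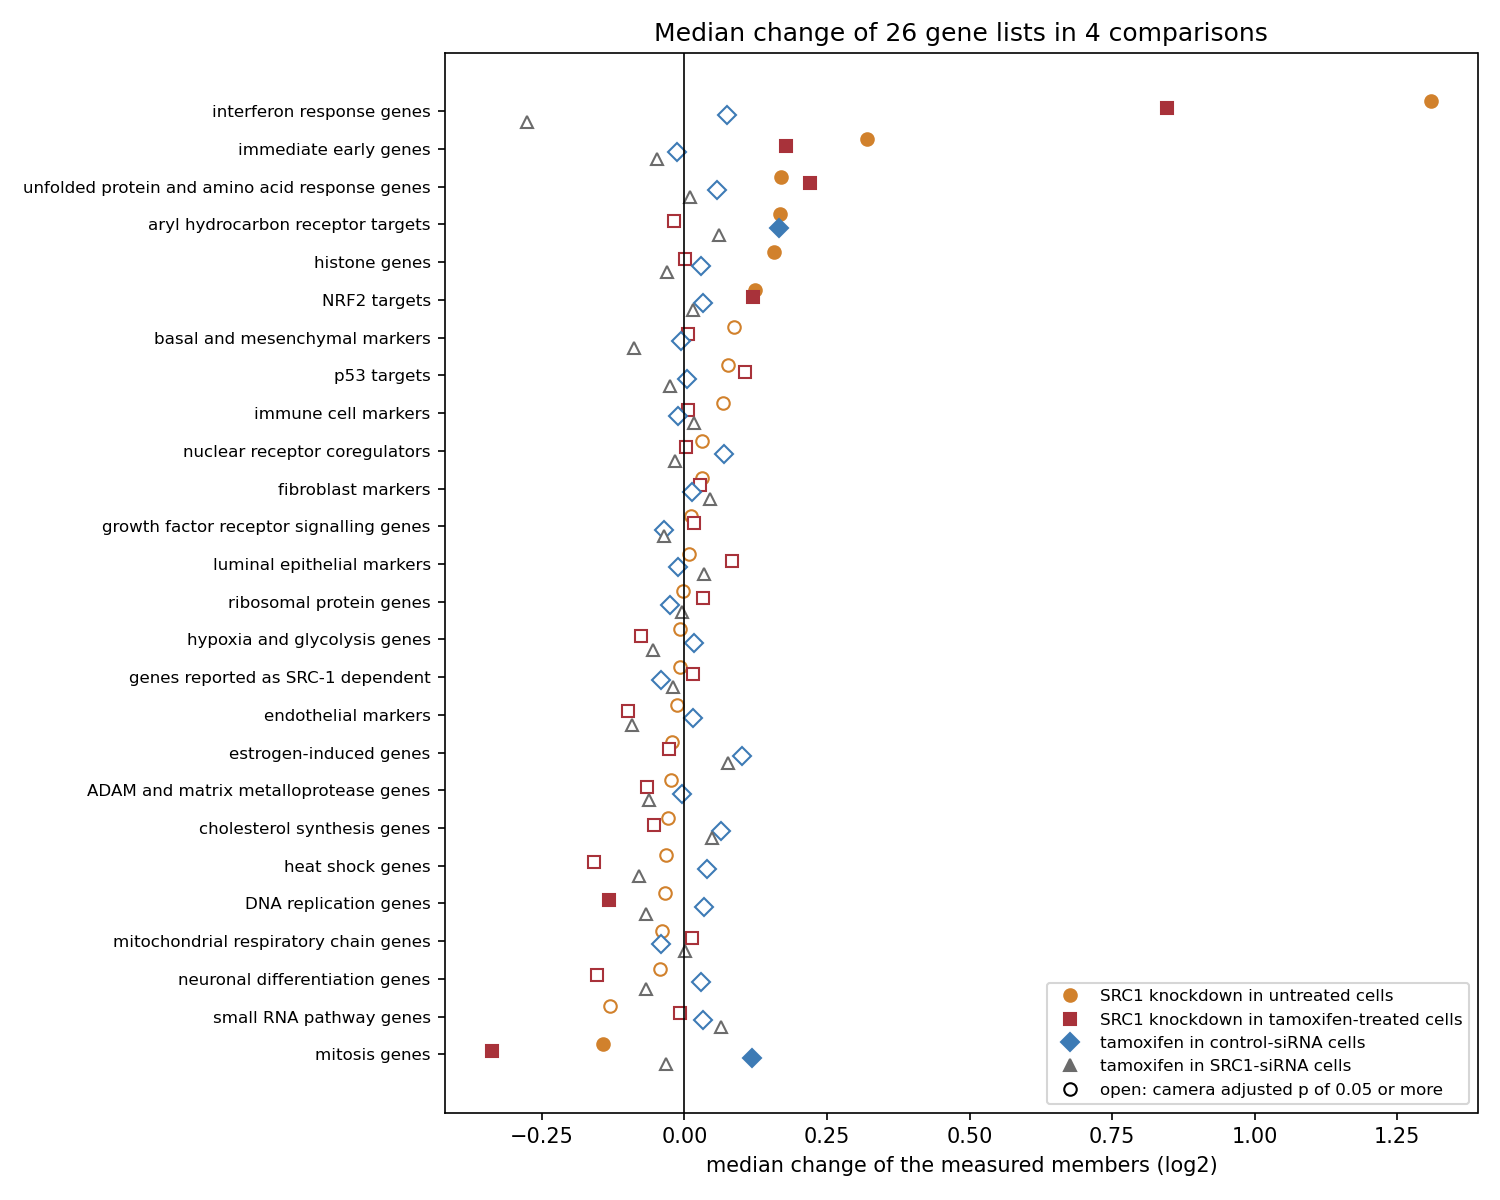
Median change (log2, horizontal axis) of the measured members of 26 gene lists (vertical axis) in 4 comparisons, with filled symbols where the camera adjusted p was under 0.05 at the preset correlation. Interferon response genes had the highest median in untreated cells (1.31) and mitosis genes the lowest in tamoxifen-treated cells (-0.34); 0 of the 104 tests passed with an estimated correlation.

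The same knockdown was compared in tamoxifen-treated cells, with 2 SRC1-siRNA arrays against 4. These 2 arrays did not cover every replicate number, so the changes may be shifted if differences between numbers had been removed. VANGL2 (6.02 ± 0.59, adjusted p = 3.26e-04), CCL5 (5.87 ± 0.61, adjusted p = 4.57e-04), SCN3A (a lower bound of 5.26, from a floor level of 2.05), HLA-DRA (5.04), CXCL11 (4.87), HLA-DPA1 (4.86), CD74 (4.80) and CEACAM1 (4.23) were again among the largest rises, with the complement factor CFB (4.58) and RGS2, which shortens G protein signals (4.26). The largest falls were in the dynein chain DYNC1I2 (-1.74 ± 0.14, adjusted p = 2.93e-04), NFIA (-1.74), the protein kinase A inhibitor PKIA (-1.70), SLC25A3 (-1.64), ACO1 (-1.63), SSX2IP (-1.63), MEIOC (-1.62), REEP1 (-1.62), SYNC (-1.56) and USP31 (-1.54). The dimmer groups of VANGL2 (3.34), DYNC1I2 (3.04) and ACO1 (2.99) lay below the median signal, where differences can be compressed, so their ranks are uncertain. The NFIA value is again that of its most changed probe set. HLA-DRA, CXCL11 and REEP1 are given here by another probe set than in untreated cells, so their values cannot be compared between treatments. The CXCL11 probe set named in untreated cells, where it changed by 4.64, changed by 4.44 here. All 20 genes also passed with the replicate number as a term. In all, 7350 probe sets passed, 3147 higher and 4203 lower. The share that was higher depended on scaling, 42.8% as deposited and 33.1% with median centring, where 2653 of 8019 were higher. With the replicate number as a term 1224 passed, in a fit of only the arrays compared 4025, without SRC1 siRNA tamoxifen replicate 1 1390, and without SRC1 siRNA tamoxifen replicate 3 4190.

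Mitosis genes fell as a list in tamoxifen-treated cells: of 22 members 9 were lower and 0 higher, or 18 and 0 adjusted over the list alone (median -0.34, camera adjusted p = 5.23e-07; adjusted p = 0.710 with an estimated correlation). They included the kinase NEK2 (-0.54) and the cyclin CCNB2 (-0.54), the 2 that passed with the replicate number as a term, and the motor KIF23 (-0.66), which did not. DNA replication genes had 5 of 22 members lower and 0 higher, also adjusted over the list alone (median -0.13, camera adjusted p = 0.0423; adjusted p = 0.710 with an estimated correlation). This call ended in several alternatives, among them the fit with the replicate number (adjusted p = 0.0740) and the fit without SRC1 siRNA tamoxifen replicate 1 (adjusted p = 0.374), within a range of 0.00848 to 0.710 over all fits. Interferon response genes had 6 of 28 members higher and 0 lower, or 7 and 0 adjusted over the list alone (median 0.85, camera adjusted p = 4.91e-06; adjusted p = 0.711 with an estimated correlation, and 0.192 with fry), led by ISG20 (3.21), MX2 (2.98) and HERC5 (2.58), of which ISG20 passed with the term, as did MX1 (1.09). Replicate 4 was present here only among the controls, and without it the median was 0.57 with 9 members higher and 0 lower (camera adjusted p = 3.10e-09; adjusted p = 0.868 with an estimated correlation). Immediate early genes had 4 of 22 members higher and 0 lower (median 0.18, camera adjusted p = 0.0121; adjusted p = 0.717 with an estimated correlation). The call ended without control siRNA tamoxifen replicate 1 (adjusted p = 0.158) or SRC1 siRNA tamoxifen replicate 3 (adjusted p = 0.0636) and with fry (adjusted p = 0.291). Unfolded protein and amino acid response genes had 4 of 20 members higher and 1 lower (median 0.22, camera adjusted p = 0.0183; adjusted p = 0.273 with an estimated correlation). NRF2 targets had 3 of 16 higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.12, camera adjusted p = 0.0423; adjusted p = 0.710 with an estimated correlation). This call ended without SRC1 siRNA tamoxifen replicate 1 (adjusted p = 0.167) or control siRNA tamoxifen replicate 1 (adjusted p = 0.144) and with fry (adjusted p = 0.0989). When the replicate number was a term 0 members of the DNA replication and unfolded protein lists passed in limma (5 and 4 at an unadjusted p under 0.05), 1 immediate early gene, EGR3, did, and 2 NRF2 targets, HMOX1 and AKR1B10, did. The other 20 lists did not pass with camera. With fry, 4 of them did: heat shock genes (adjusted p = 0.0120), endothelial markers (adjusted p = 0.0196), hypoxia and glycolysis genes (adjusted p = 0.0374) and neuronal differentiation genes (adjusted p = 0.0475).

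The knockdown comparisons in untreated and in tamoxifen-treated cells shared no arrays. They had 1187 higher probe sets in common, where 157 would be shared by independent lists, and 1217 lower ones, where 225 would be. When the replicate number was a term they had 365 and 262 in common, where 11.9 and 12.2 would be. Across the 27306 probe sets above the median signal, changes correlated at r = 0.760, a value across genes, which are not independent replicates. In the additive fit over both treatments 9296 probe sets passed for the siRNA, 4138 higher and 5158 lower, and 5031 with the replicate number as a term. The genes with the largest changes there were those already named, with the chromatin remodeller HELLS added among the falls (-1.26 ± 0.11, adjusted p = 1.10e-05).

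Tamoxifen in control-siRNA cells was compared to ask what a 2-hour exposure changed where SRC-1 was present. PHLDA1, a gene of the pleckstrin homology-like family, rose at 1 of its probe sets from 8.71 to 9.33 (0.62 ± 0.05, adjusted p = 4.11e-04). It was the only probe set to pass with the replicate number as a term (adjusted p = 0.0154), and was named after its values were seen. The other named genes passed only without that term. With the mean of a gene's probe sets, 16 of 22 named genes and list members did not pass in limma and 6 did. KLHL5 (0.67), a further PHLDA1 probe set (0.63), GLT8D2 (0.59), DCAF5 (0.49), the Hippo pathway kinase STK3 (0.47), the mitotic kinase NEK2 (0.47), EHD1 (0.46), FAM76B (0.43), CD47 (0.42) and DEGS2 (0.41) were higher. The cyclic AMP phosphodiesterase PDE4B (-0.99), the transcription factor MYC (-0.81 ± 0.13, adjusted p = 0.0343), NHSL2 (-0.78), C5orf63 (-0.63), NCAM1 (-0.61), the cytokine signalling inhibitor CISH (-0.60), IGFBP5 (-0.58), TCIRG1 (-0.57), ZNF701 (-0.52) and CMIP (-0.51) were lower.

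In all, 89 probe sets passed for tamoxifen in control-siRNA cells, 39 higher and 50 lower. With the replicate number as a term 1 passed, in a fit of only the arrays compared 2 did, and leaving out single arrays gave between 1 and 68. In simulated arrays with no effect, from which differences between replicate numbers had been removed, the fit without the term gave 10.4% of probe sets an unadjusted p under 0.05 and called 22, and the fit with the term gave 5.05% and called 0.

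Of the lists, mitosis genes were higher with tamoxifen, with 1 of 22 members passing, NEK2, or 2 adjusted over the list alone (median 0.12, camera adjusted p = 4.21e-04; adjusted p = 0.710 with an estimated correlation, and 0.104 with fry). This comparison and the knockdown comparison in treated cells share the control-siRNA tamoxifen arrays. Without the arrays of replicate 4, whose untreated control array had the lowest mean of this list in its group, the median was 0.05 and the adjusted p 0.0882. Targets of the aryl hydrocarbon receptor had a median of 0.17 (camera adjusted p = 0.00155; adjusted p = 0.127 with an estimated correlation) with 0 of 10 members passing in limma over all probe sets, 2 higher adjusted over the list alone and 6 higher at an unadjusted p under 0.05. For that receptor's targets, this comparison and the knockdown in untreated cells share the control-siRNA untreated arrays, so the rises in both are not independent. In treated cells the knockdown gave these targets a median of -0.02, with 0 of 10 members passing in limma. Of 28 estrogen-induced genes 1, MYC, was lower, or 6 were higher and 1 lower adjusted over the list alone, and the list did not pass (median 0.10, camera adjusted p = 0.0743). It did pass without the arrays of replicate 4 (median 0.15, adjusted p = 2.30e-04; adjusted p = 0.338 with an estimated correlation).

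Tamoxifen in SRC1-siRNA cells was compared with 2 treated arrays against 4. Here too the changes may be shifted if differences between replicate numbers had been removed, as the treated arrays lacked some numbers. Genes that rose were FAM184A (1.29 ± 0.21, adjusted p = 0.0126), the poly(A) polymerase PAPOLA (1.21 ± 0.17, adjusted p = 0.0117), the splicing factor U2SURP (1.18), the apoptosis regulator CFLAR (1.16), the ubiquitin ligase SMURF1 (1.16), TTLL5 (1.16), VPS13C (1.14), DNAI4 (1.13), LOC100505915 (1.11) and the ATP synthase subunit ATP5F1C (1.10). Genes that fell were the lamina protein TMPO (-1.14 ± 0.15, adjusted p = 0.00632), DYNC1I2 (-1.10), SYNC (-1.02), the histone H2AC15 (-0.99), SSX2IP (-0.95), SLC15A2 (-0.90), COG6 (-0.90), BCL10 (-0.88), CSPG5 (-0.83) and AFF3 (-0.83). DYNC1I2 and COG6 fell below the median signal (3.04 and 3.31), so their ranks are uncertain. Each value is that of 1 probe set, and the gene's other probe sets may differ. Standard errors pool the spread of all groups, whereas the SD between the 2 treated arrays ranged widely, from 0.01 for SMURF1 to 0.52 for TMPO and 0.61 for DNAI4. With the mean of a gene's probe sets, 16 of 22 named genes and list members did not pass in limma and 6 did. In all, 824 probe sets passed, 494 higher and 330 lower. None passed in limma with the replicate number as a term. Without the term 9178 of 54613 probe sets had an unadjusted p under 0.05. In simulated arrays with no effect and number differences removed, 10.4% of probe sets had such a p for tamoxifen in control-siRNA cells. No such simulation was run here, so 9178 has no null value to be set against. Most of the 824 calls ended without SRC1 siRNA tamoxifen replicate 1, which left 1 treated array.

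Of the 26 lists 0 passed in camera for tamoxifen in SRC1-siRNA cells, although estrogen-induced genes (median 0.08, adjusted p = 0.0601) did with the replicate number as a term (adjusted p = 0.0267) and without the arrays of replicate 4 (median 0.12, adjusted p = 2.92e-04; adjusted p = 0.338 with an estimated correlation). Over all arrays their adjusted p was 0.711 with an estimated correlation. The coregulator NRIP1, also an estrogen-induced gene, was higher (0.71), and neither it nor any other list member passed with the replicate number as a term. The endothelial cadherin CDH5 also passed, between dim levels near the floor (2.61 and 2.25), so no fall is drawn from it. With fry 1 list passed, endothelial markers (median -0.09, adjusted p = 0.0230). Of the 824 probe sets 53.2% had a mean below the median signal. No single gene symbol was carried by 54.9% of those higher and 22.1% of those lower, against 24.8% of all probe sets. Median centring, which set 45.4% of the called probe sets higher, differed here from the deposited values, with 60.0%. The same PHLDA1 probe set was at 8.91 and 9.51 without and with tamoxifen in these cells, a difference of 0.60. Tamoxifen in control-siRNA and in SRC1-siRNA cells had 4 higher probe sets in common, where 0.353 would be shared by independent lists, and 5 lower ones, where 0.302 would be, and changes correlated at r = 0.04 across probe sets. Another 2 probe sets were lower in control-siRNA cells and higher in SRC1-siRNA cells. With the replicate number as a term none was shared, since none passed in SRC1-siRNA cells.

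The interaction tested directly whether tamoxifen acted differently with and without the knockdown. It passed for 153 probe sets, 73 higher and 80 lower, and for 0 in limma with the replicate number as a term. The size of an interaction may likewise be shifted if differences between numbers had been removed. Most of the 153 calls ended without SRC1 siRNA tamoxifen replicate 1, which left 1 array in that group. Without the term 9444 probe sets had an unadjusted p under 0.05, and no simulation without effect was run for the interaction to set this count against. TMPO had the largest interaction of the named genes (-1.71 ± 0.19, adjusted p = 0.00924). Its SD was 0.52 between the 2 SRC1-siRNA tamoxifen arrays and 0.07 to 0.12 in the other groups, so this pooled standard error may overstate the precision.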

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

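The tests of immune cells, SRC1 dose, siRNA response, replicate 4, near-floor signal and removed number differences were chosen only after the result was seen. All tests of the larger count for tamoxifen in SRC1-siRNA cells, and of its probe sets that were not the brightest, also concern patterns known only from the results.

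For the rise of interferon response genes with SRC1 siRNA, immune cells mixed into the cultures are argued against, since the immune markers other than CD74 had a median change of 0.0561 with an upper bound of 0.125, and the highest, LYZ, changed by 0.39 and reached only 3.65. That bound is a 95% bootstrap bound over 13 marker genes and does not measure the spread between arrays. The markers lay near the floor (median level 2.44 in control-siRNA and 2.41 in SRC1-siRNA untreated cells), so a small share of such cells could go unseen. Replicate 4 alone is argued against for the list as a whole, since the median without its 3 arrays was 0.537, though IFIT1, IFIT2, IFIT3, XAF1, IFI44 and HERC6 differed mainly there. Loss of SRC1 in proportion stays open, because across the 6 SRC1-siRNA arrays NCOA1 and the list correlated at r = 0.696 (exact permutation p = 0.115, adjusted 0.288 over 5 relations; rho = 0.886, exact permutation p = 0.0333, adjusted 0.0833; r = 0.834 without the 2 farthest arrays), where a proportional loss needs a negative r, while IFNB1 and NCOA1 gave r = 0.947 (exact permutation p = 0.0222, adjusted 0.111). Replicates 1 and 3 each gave an untreated and a treated array, so the 6 arrays may not be independent and these p-values may be too small. Removal of number means, if it was done, would also distort levels across numbers. Within replicate numbers 1 to 4, untreated, the list differed by 1.55, 0.61, 0.43 and 3.64 and NCOA1 by -0.80, -1.60, -2.00 and -0.79, so that the list rose least where NCOA1 fell most, which goes against a proportional loss but rests on 4 differences. A response to the siRNA duplex may also explain the pattern, as IFNB1 rose by 3.98, but 1 siRNA per target cannot tell it apart from loss of SRC1.

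More probe sets passed for tamoxifen in SRC1-siRNA cells (824) than in control-siRNA cells (89). A treated group of 2 arrays is, by its size alone, argued against as the cause, as the highest count over 6 pairs of control-siRNA tamoxifen arrays was 11. Those pairs came from a group that held every replicate number. They cannot show what removal of number means, if it was done, did to a group with only replicates 1 and 3. Signal near the floor is argued against as the whole cause, as 386 of the calls lay above the median signal against 70 in control-siRNA cells. A single deviating array may be the source, since without SRC1 siRNA tamoxifen replicate 1 only 3 passed, although 656 passed without replicate 3 and 0 with the replicate number as a term; that array had the highest hybridization spikes (12.3, next 12.1), median (3.51, next 3.49) and GAPDH 3'-5' difference (0.973, next 0.915) of all 14, but not the highest actin 3'-5' difference (3.27, highest 3.45). A biological difference in the tamoxifen response stays open and rests on those 2 arrays.

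Arrays with the same replicate number tended to deviate in opposite directions, with a median correlation of -0.353 over 18 pairs and a highest of 0.0445. Differences between the numbers may have been removed before the values were deposited, since 77.8% of probe sets had a replicate-number F in the lowest 5% of its null distribution. The array maximum fits a shift made after normalization: it was 15.5 in SRC1 siRNA untreated replicate 4 and 14.3 or less elsewhere. IFIT1 was at 15.5 in that array and at 9.76 in the untreated control of the same number, and removal of a number's mean could lower controls that share it with a strongly changed array. No biological explanation was tested.

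Where 35 splits were counted, the real split was balanced over replicate numbers. That of the additive fit was not fully balanced, as SRC1 siRNA with tamoxifen had only replicates 1 and 3. Most other splits were less balanced, which favours the real ones if number means were removed, so the splits alone do not exclude chance. For the knockdown in untreated cells 1 of 35 splits, the real one with 5653 calls, gave as many and the highest other gave 3. For the knockdown over both treatments it was 1 of 100, with 9296 calls and a highest other of 30 in the draw kept, a value that changed with the draw. Simulated arrays without effect and with number means removed gave 31 calls in untreated cells. Their noise was independent between probe sets, whereas interferon response genes had an estimated correlation of 0.796, so this count does not bound what chance gives. No such simulation was run for the knockdown over both treatments. The fits with the replicate number as a term called 2154 and 5031, which argues against chance for both comparisons but does not exclude it. For tamoxifen in control-siRNA cells it was 1 of 35, with 89 calls and a highest other of 0, but the same simulation gave 22 calls and the fit with the replicate number 1, so chance was not excluded for most of the 89.

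In 25 of 645 groups of 4 arrays, or 3.88%, 1 array stood apart by the ratio of its gap to the range, where chance gives about 5%. For control siRNA untreated replicate 4 this held for the mean of the mitosis genes (ratio 0.890), AURKA (0.911), CCNB1 (0.868) and NEK2 (0.882), all lowest there, and MUC1 (0.855), highest. Control siRNA untreated replicate 1 was highest for MYC (0.854), PKIA (0.878) and USP31 (0.883) and lowest for LOC100505915 (0.847). Control siRNA untreated replicate 2 was highest for CMIP (0.914) and lowest for PDIA4 (0.852), and replicate 3 was highest for BAX (0.891). Control siRNA tamoxifen replicate 1 was lowest for EGR3 (0.980), EGLN3 (0.946), PIK3R1 (0.926) and SPRY2 (0.921), replicate 2 for PAPOLA (0.978) and GINS2 (0.871), and replicate 4 for IFI27 (0.927), while H2BC21 was highest in replicate 4 (0.852). SRC1 siRNA untreated replicate 4 was highest for IFI27 (0.843) and in its array maximum (0.981), and replicate 2 was highest for CDH5 (0.938) and lowest for CHORDC1 (0.833) and IRS2 (0.830).

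The effect of the knockdown differed between untreated and tamoxifen-treated cells by the interaction test for 7 named genes. The interaction was -1.71 for TMPO, -1.24 for DYNC1I2, -1.23 for SYNC, -0.41 for H3C2, 0.57 for CMIP, 1.29 for PAPOLA and 1.45 for LOC100505915, and no interaction passed with the replicate number as a term.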

How the results depend on the processing

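Leaving out all arrays of a replicate number was chosen only after the result was seen. With the replicate number as a term the counts were 2154 for the knockdown in untreated cells, 1224 in tamoxifen-treated cells, 5031 over both treatments, 1 and 0 for tamoxifen in control-siRNA and SRC1-siRNA cells, and 0 for the interaction. None of the 18 same-number correlations passed 0.1, and 0 of 14 arrays correlated best with an array of its own number, which removal of number means would force, so these correlations do not show whether the numbers pair the arrays. The mean of a gene's probe sets gave 2784, 3422, 4559, 48, 88 and 22 in the same order, by construction fewer tests. A fit of only the arrays compared gave 4025 for the knockdown with tamoxifen, 2 for tamoxifen in control-siRNA cells and 109 in SRC1-siRNA cells, with fewer arrays. Median centring gave 35 and array weights 232 for tamoxifen in control-siRNA cells, weights 371 in SRC1-siRNA cells, and leaving out dim probe sets 246 there and 23 for the interaction; the cause was not tested. Leaving out single arrays gave 3626 to 5750, 1390 to 7215, 7358 to 9374, 1 to 68, 3 to 879 and 7 to 346. Leaving out all arrays of numbers 1 to 4 gave 3066, 1953, 3071 and 4447 for the knockdown untreated, 1183, 3587, 2742 and 5991 with tamoxifen and 4158, 5714, 6000 and 8566 over both. It gave 11, 0, 0 and 24 for tamoxifen in control-siRNA cells, 7, 119, 307 and 159 in SRC1-siRNA cells, and 3, 0, 4 and 0 for the interaction. Of 104 list tests 15 passed with camera, 0 with an estimated correlation, 11 with fry, of which 6 were among the 15, and 12 to 17 without single arrays. NCOA1 kept its direction in every alternative run, and its call in all but the knockdown with tamoxifen without SRC1 siRNA tamoxifen replicate 3, between -1.40 and -1.16 untreated and -1.50 and -1.15 with tamoxifen without single arrays. Median centring set 36.2% of the interaction calls higher, against 47.7% as deposited. With the mean of a gene's probe sets the change reversed for RRM1 (0.0104), NRCAM (0.0196) and PRKRA (0.0200) untreated, and HERPUD1 (-8.73e-04) and ADAM9 (0.0297) with tamoxifen; the cause was not tested. A scale of log2(value + 1) was not run, as the values were already on a log scale.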

Other observations

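The 5 lists of this part were chosen only after the result was seen, on the same arrays, and so describe the rise and do not test it independently. Their tests were adjusted among themselves, a smaller family than the 104 tests of the fixed lists, so adjusted p-values cannot be compared between both. With an estimated correlation, a camera p of 0.0172 for MHC class II genes became 0.0490 here. In the larger family, 0.00142 for unfolded protein and amino acid response genes in untreated cells became 0.127. Passing here therefore does not set these lists apart from the fixed ones.

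Antigen presentation genes rose with SRC1 siRNA in untreated cells. Of 15 MHC class I and antigen processing genes 15 were higher (median 1.09, camera adjusted p = 2.88e-13; adjusted p = 0.0490 with an estimated correlation), among them the immunoproteasome subunit PSMB9 (1.51), the class I regulator NLRC5 (1.98) and HLA-F (1.84). Of 13 MHC class II genes 9 were higher and 0 lower (median 2.19, camera adjusted p = 1.20e-09; adjusted p = 0.0490 with an estimated correlation), with HLA-DMB (3.04) and the class II transactivator CIITA (0.74, from a dim 3.36) higher. Probe sets of HLA genes can bind near-identical members, so which member changed is uncertain. Of 16 chemokine genes 12 were higher and 1, CCL8, lower at signals near the floor in both groups (median 1.45, camera adjusted p = 2.85e-10; adjusted p = 0.0424 with an estimated correlation), with CXCL8 (3.28), CCL22 (3.25) and CX3CL1 (a lower bound of 2.32, from a floor level of 2.26) higher.

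Of 14 NF-kappa-B feedback genes 9 were higher and 0 lower (median 0.51, camera adjusted p = 4.93e-08; adjusted p = 0.0589 with an estimated correlation), with the deubiquitinase TNFAIP3 (1.48), TNF (1.24, from a dim 2.68) and IL6 (1.49, from a dim 3.35) higher. Of 8 metallothionein genes 5 were higher and 0 lower (median 0.54, camera adjusted p = 1.02e-06; adjusted p = 0.0424 with an estimated correlation), with MT1X (0.85) and MT1F (0.68) higher, where again near-identical members cannot be separated. With the replicate number as a term 10, 8, 10, 7 and 3 members were higher in the order given, and of the genes named NLRC5 and CIITA did not pass. With tamoxifen the same lists had 12, 10, 8, 7 and 5 members higher in the order given (7, 8, 6, 4 and 1 with the term). For tamoxifen itself 0 members of these lists passed in limma, and only the MHC class II list passed in camera, in SRC1-siRNA cells (median 0.25, adjusted p = 0.00255; adjusted p = 0.325 with an estimated correlation).

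Of the 223 probe sets with a single gene symbol that were higher with tamoxifen in SRC1-siRNA cells, 157 or 70.4% were not their gene's brightest probe set, against 51.9% of all. A rise of the whole gene's transcripts was argued against, since the brightest probe sets of the same genes had a median change of 4.33e-04, where the called ones had 0.53. The called probe sets were selected for passing and the brightest were not, so false calls would give the same pattern. None of the calls passed with the replicate number as a term, so false calls were not excluded. What kind of transcript those probe sets measured was not tested.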
